A study of Homo sapiens with 11 samples.

How the data were processed

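RNA from cultured human pulmonary artery endothelial cells was measured on Illumina expression BeadChips, arrays that carry oligonucleotide probes on beads and report the brightness of bound, biotin-labelled cRNA. Per the labels' protocols, commercially supplied cells at passage 5 were transfected for 24 h with siRNA duplexes against beta-catenin, against the type II bone morphogenetic protein receptor (BMPRII), or with a non-targeting control. They were then kept overnight in basal medium with 0.5% serum, and 250 ng of RNA per sample was extracted. The 11 samples form 3 groups, with 4 control, 4 beta-catenin and 3 BMPRII samples. Nothing in the labels says that the samples of a group came from separate cultures or donors, so the p-values measure the spread between these samples, which may be technical. The labels name no chip, date or batch.

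The deposited table of raw values holds an intensity and a detection p-value for 37670 rows on each array, not normalized between arrays per the file headers. It was made with BeadStudio per the submitters' processing notes, with no version given. From the values, background had already been subtracted, since 28.7% to 32.0% of the intensities on an array lie below 0. The detection p-value deposited beside each intensity sets the row against 759 negative control probes of the same array. In 6206 rows (16.5%) it took values that a single probe cannot give. Of these, 3255 had the pattern of a mean over 2 probes and 1199 over 3, so such rows combine several probes of a gene. A second deposited table holds the authors' processed intensity values on a linear scale. Each of its columns equals the raw column under a single slope (0.77 to 1.45) and a single offset (-2.18 to 2.84) to within 0.0121 intensity units. Its method is not given in the sources used here, and the column medians were 6.29 to 10.2. No genome build is given in the sources used here, and no coordinates are printed.

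Here the raw table was used. The design fixed before the data were examined asked for the neqc procedure, which estimates the background from detection p-values when control probes are absent. Because the rows that combine probes distort that estimate, the background was estimated on the 31464 rows whose p-value is a whole number of negative controls. The estimated mean of the negative controls then lay between -0.00079 and 0.00052 over the arrays, with a standard deviation of 10.9 to 16.0. Background was corrected with normexp, 16 was added, log2 was taken, and arrays were quantile normalized. All fold changes are on this log2(intensity + 16) scale, which understates changes of dim genes. Rows with a detection p under 0.05 on at least 3 samples were tested. Removing 73 rows of Y-linked genes and XIST left 13497 tested rows. For a row not detected on any array of a group, a fold is given as a lower bound, from the bright group's mean against the higher, per array, of the dim row's own value and the lowest detected value.

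Probes were named from the platform annotation with symbols updated through gene identifiers (19135 matched). A single symbol was given for 19161 rows, several symbols for 13 and none for 18496. Rows are called features below. At gene level, the tested row with the highest mean over all samples stood for a gene, giving 10449 genes. A list's members are counted at gene level.

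Linear models were fitted with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the package data.table, on all 11 arrays with a mean per group and a shared spread (8 residual and 4.17 prior degrees of freedom). The 3 contrasts were each knockdown minus control, and BMPRII minus beta-catenin siRNA. Benjamini-Hochberg adjusted p-values under 0.05 count as called. The siRNA targets and the genes of the study's question were also compared by exact two-sided permutation tests. Gene lists fixed before the data were examined (25 lists) were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjustment was over the lists within a contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

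Genes are named by a rule written before the data were examined. It takes CTNNB1, BMPR2, APLN, PPARG, ID1 and AXIN2 always, and the 10 largest rises and 10 largest falls per knockdown among called genes whose knockdown samples all lie on the same side of the control mean. It also takes up to 4 members of each list with the smallest p, the 5 strongest genes per direction called in both knockdowns, 5 per direction called in opposite directions, and the 5 largest per direction between the knockdowns. Unnamed rows and provisional names are passed over. Any other gene named below is marked as chosen after its values were seen.

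In data simulated from the means and spreads of the 13497 tested features, with 5 simulations of 50 changed features per fold size, the beta-catenin contrast recovered 50% of 1.5-fold, 83.6% of 2-fold, 96.8% of 3-fold and 99.6% of 4-fold changes. The BMPRII contrast recovered 40.4%, 79.2%, 96.4% and 99.2%. False calls made up 5.7% and 5.3% of all calls. The simulated noise was independent between features and had the same spread in all groups. These shares therefore do not cover deviations that features of an array have in common, or the wider spread of the control arrays. Unchanged groups simulated with the arrays' own deviations gave up to 1185 features called lower in both knockdowns in a single simulation.

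The alternatives tried were the replicate number as a block, no background correction, median scaling, the authors' processed table, no filter, 2 stricter filters, an offset of 50, only the compared groups in the fit, array weights, an intensity trend, and leaving out each sample in turn. For the overlap, the controls were split into pairs, and for the lists the row of a gene was also chosen by an F test. Leaving out control replicates 1 and 4, which correlated least with the other arrays, was chosen after seeing the data. The chip as a block was not run, because the files used here name no chips. The number of arrays limits the precision.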

Results

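Gene expression was measured in human pulmonary artery endothelial cells, the cells that line the artery from the heart to the lung, after siRNA against beta-catenin (4 samples), siRNA against BMPRII (3 samples) or a non-targeting control siRNA (4 samples). Beta-catenin is the transcriptional effector of canonical Wnt signalling and a component of adherens junctions. BMPRII is a receptor for bone morphogenetic proteins (BMPs) whose gene is mutated in heritable pulmonary arterial hypertension. On each array 11722 to 13018 of 37670 rows (31.1% to 34.6%) were detected, and the mean raw intensity ran from 221 on control replicate 4 to 456 on control replicate 3. The control arrays spread more than the others, with a residual SD of 0.28 on the log2 scale against 0.20 in the beta-catenin and 0.22 in the BMPRII group. The mean correlation of an array with the others of its group was 0.981 or more across features, which are not independent replicates.

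The siRNA targets were examined first. CTNNB1, which encodes beta-catenin, fell from 7.94 ± 0.13 (log2 intensity, mean ± SD, n = 4) in control cells to 5.30 ± 0.15 (n = 4) after beta-catenin siRNA, leaving 10.2% of the mean control intensity (normalized, without the added 16). BMPR2, which encodes BMPRII, fell from 10.12 ± 0.09 (n = 4) to 6.66 ± 0.33 (n = 3) after BMPRII siRNA, leaving 7.88%. Each fall separated all samples of the groups (exact two-sided permutation p = 0.0286, the smallest these group sizes allow). The adjusted p from limma was 1e-07 for CTNNB1 and 2.39e-07 for BMPR2. In the other knockdown, BMPR2 differed from control by 0.22 ± 0.14 (log2 fold change ± SE, adjusted p = 0.301) and CTNNB1 by -0.37 ± 0.11 (adjusted p = 0.0931), which left 75.4% of its mean control intensity. The exact permutation p was 0.0857 for the former and 0.0286 for the latter, so CTNNB1 also lay below every control on all 3 BMPRII arrays. Adjusted over the siRNA targets alone, both were called lower after BMPRII siRNA. Each gene had 1 row, which combined several probes.

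The study is known to have been concerned with genes that BMPRII and beta-catenin control together, among them APLN, which encodes the secreted peptide apelin. APLN fell by 2.51 ± 0.12 on the log2 scale (SE, adjusted p = 2.41e-07) after beta-catenin siRNA, to 16.9% of the mean control intensity. It fell by 1.28 ± 0.13 (adjusted p = 0.000232) after BMPRII siRNA, to 40.6%. The fall was larger after beta-catenin siRNA, by 1.23 ± 0.13 (adjusted p = 4.96e-05 for the difference). ID1, a classical transcriptional target of BMP signalling, fell by 0.99 ± 0.13 (adjusted p = 0.000377) after beta-catenin siRNA. After BMPRII siRNA its log2 fold change was -0.07 ± 0.15 (adjusted p = 0.87), and the knockdowns differed by 0.92 ± 0.15 (adjusted p = 0.000932). The row of ID1 combined several probes and was detected on 3 control arrays, 1 beta-catenin array and 3 BMPRII arrays. PPARG, which encodes the nuclear receptor PPARγ, was detected on 1 of the 11 arrays and AXIN2, a negative feedback gene of Wnt signalling, on 0. Both were therefore left out of the limma fit, and no fold is given for them. On these values near background, exact permutation tests against control gave p = 0.0286 for each gene after BMPRII siRNA, and p = 0.514 for PPARG and p = 0.4 for AXIN2 after beta-catenin siRNA.

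**Figure D1:**
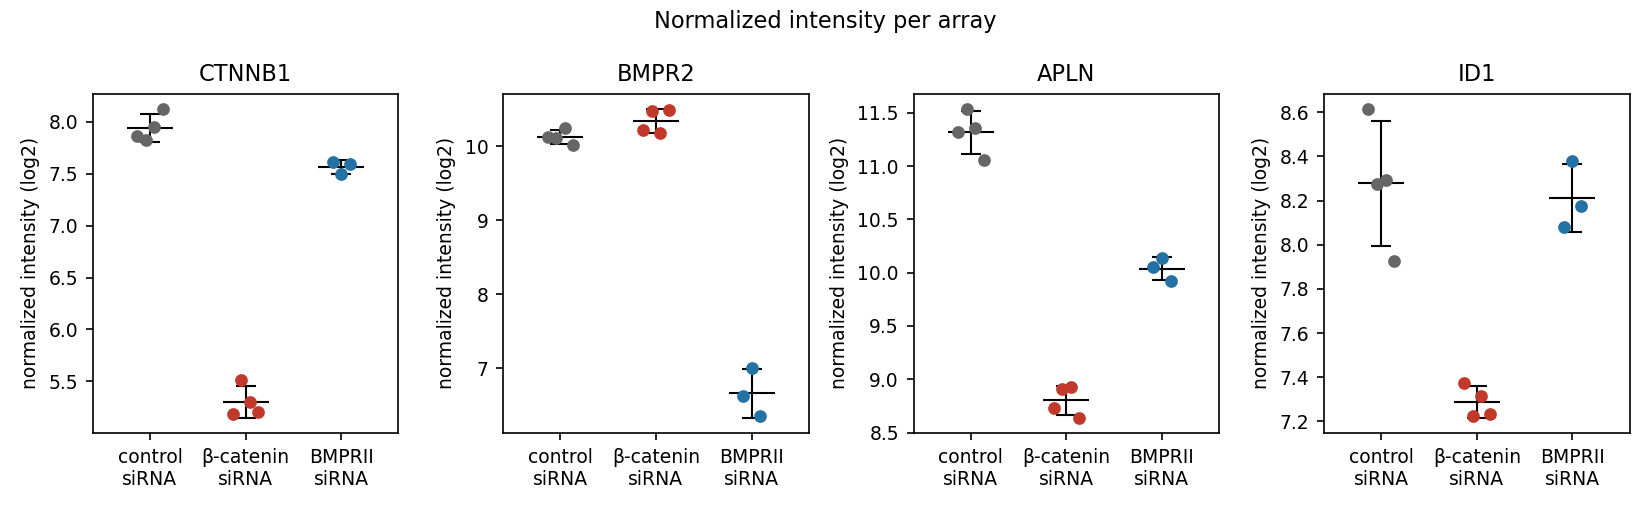
Normalized intensity (log2) of CTNNB1, BMPR2, APLN and ID1 on each array, by siRNA group. Points are arrays, and bars are the mean and SD of the group (n = 4, 4 and 3). APLN lay at 11.3 on average in control cells, at 8.80 after beta-catenin siRNA and at 10.04 after BMPRII siRNA.

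Among the largest changes after beta-catenin siRNA, LYVE1, a hyaluronan receptor best known from lymphatic endothelium, fell 4.56-fold, CLDN5, the main claudin of endothelial tight junctions, 3.66-fold, and CD34, a sialomucin of vascular endothelium, 3.4-fold. Named genes outside the lists also fell far: GTF2H5, a subunit of the repair and transcription factor TFIIH, 4.99-fold, COX7A2, a subunit of cytochrome c oxidase, 4.39-fold, MGLL, which encodes monoacylglycerol lipase, 3.82-fold, and MALL 3.68-fold. ADGRF5 and POGLUT3 fell 3.52-fold and 3.41-fold. Rises were led by H2BC5, a histone H2B gene (4.34-fold), RSAD2, an interferon-induced antiviral gene (3.41-fold), KCNS1 (3.22-fold), CXCL10, an interferon-induced chemokine (3.14-fold), AHSA2P (3.03-fold) and MET, the hepatocyte growth factor receptor (3.01-fold). FLRT3, MAL2, AKR1C2 and CH25H were not detected on any control array and rose at least 3.42-fold, 3.09-fold, 2.86-fold and 2.76-fold. In all, 2578 of 13497 features (19.1%) were called, 1301 higher and 1277 lower, and 275 of them changed over 2-fold (89 higher, 186 lower).

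The list of Wnt and beta-catenin targets was lower as a whole (camera adjusted p = 0.0175; adjusted p = 0.103 with an estimated correlation), with 6 of 18 measured members lower, 1 higher and 11 not called. Adjusted over the list alone, the counts were the same. Its leading members were CCND1, the cyclin of G1 entry (-0.99 ± 0.10, log2 fold change ± SE), CD44 (-1.02 ± 0.12), the matrix proteoglycan gene VCAN (-0.98 ± 0.13) and the urokinase receptor gene PLAUR (-0.83 ± 0.09). Of 37 measured cell cycle genes, 20 fell, none rose and the median was -0.44 (camera adjusted p = 6.93e-10; adjusted p = 0.103 with an estimated correlation), or 27 adjusted over the list alone. Examples were BIRC5 (-1.24 ± 0.20), CDC20 (-1.05 ± 0.15), the replication helicase subunit gene MCM7 (-0.70 ± 0.12) and CDC45 (-0.66 ± 0.10). The list of the unfolded protein response and of targets of the amino acid stress factor ATF4 fell, with 9 of 21 members lower and none higher (adjusted p = 0.0011; adjusted p = 0.103 with an estimated correlation), or 11 lower and 1 higher adjusted over the list alone. They included PHGDH, the entry enzyme of serine synthesis (-0.91 ± 0.13), CTH (-0.81 ± 0.18), ASNS, asparagine synthetase (-0.58 ± 0.11), and PPP1R15A (-0.46 ± 0.10).

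Angiogenesis genes fell more often than they rose, with 13 of 35 lower and 4 higher (adjusted p = 0.0175; adjusted p = 0.103 with an estimated correlation; 15 and 4 adjusted over the list alone). Besides APLN and CD34, PGF, placental growth factor, fell by 1.35 ± 0.12, while HEY2, a Notch-responsive repressor of arterial endothelium, rose by 0.93 ± 0.09. Junction genes divided, with 5 of 22 lower and 2 higher (adjusted p = 0.0238; adjusted p = 0.103 with an estimated correlation; 6 and 2 adjusted over the list alone). CLDN5 fell by 1.87 ± 0.19, and PCDH12 was not detected on any knockdown array and fell at least 1.39-fold. The gap junction genes GJA4 (connexin 37) and GJA1 (connexin 43) rose by 1.35 ± 0.15 and 0.49 ± 0.12, the latter not called without both control replicates 1 and 4. Matrix genes fell (8 of 32 lower and 1 higher, or 9 and 1 adjusted over the list alone, adjusted p = 0.0238 and adjusted p = 0.245 with an estimated correlation), led by the metalloproteinase genes MMP14 (-1.28 ± 0.19) and MMP10 (-1.06 ± 0.13) and by THBS1, thrombospondin 1 (-0.56 ± 0.11). The junction list had an adjusted p of up to 0.12 over the alternatives and lost its call without control replicate 1 or without control replicate 3. The matrix list lost its call without control replicate 4.

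Interferon-response genes were the only list higher after beta-catenin siRNA at a preset correlation, with 13 of 35 members higher, none lower and a median of 0.57, or 15 higher adjusted over the list alone (camera adjusted p = 3.26e-06; adjusted p = 0.461 with an estimated correlation). CXCL10, RSAD2, IFIT1 (1.45 ± 0.22), IFI44 (1.02 ± 0.16) and the signalling factor gene IRF9 (0.87 ± 0.10) were among them. The mean of the list spread widely over control arrays, from -0.69 on control replicate 3 to 0.42 on control replicate 4 relative to the control mean. Without control replicate 3 the median was 0.39 (adjusted p = 0.00187 at the preset correlation).

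Neither BMP list passed camera after beta-catenin siRNA, and by fry, which tests a list without comparing it to other genes, the pathway components did (adjusted p = 0.00746) and the targets did not (adjusted p = 0.318). For both, the counts were the same adjusted over the list alone. Among BMP and SMAD targets, 5 of 18 rose and 5 fell (adjusted p = 0.994), with ID1 and LFNG (-1.13 ± 0.12) lower and the inhibitory SMAD7 (1.42 ± 0.10) and HEY2 higher. Among BMP and TGF-β pathway components, 5 of 20 rose and 3 fell (adjusted p = 0.618), including the receptor genes ACVR1B (0.84 ± 0.10) and TGFBR3 (0.83 ± 0.14) upward and ACVRL1, the endothelial BMP9 receptor ALK1 (-0.78 ± 0.12), downward. Targets of PPARγ went both ways, with 4 of 16 higher and 5 lower, or 5 and 6 adjusted over the list alone (adjusted p = 0.636, median 0.07 and mean -0.16). APLN is a member of that list, FABP4, a fatty acid binding protein of adipocytes and endothelium, fell by 1.13 ± 0.24, and the cholesterol exporter gene ABCA1 rose by 0.81 ± 0.14. Endothelial function genes likewise went both ways, with 8 of 31 lower and 5 higher, or 10 and 6 adjusted over the list alone (adjusted p = 0.357). SOX18, an endothelial transcription factor, fell by 1.43 ± 0.14, whereas PTGS1, cyclooxygenase 1, and DDAH1, which degrades an inhibitor of nitric oxide synthase, rose by 1.37 ± 0.12 and 1.15 ± 0.11.

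Of the features called after beta-catenin siRNA, 50.5% were higher. Of 2435 calls in the authors' processed table, 39.7% were higher.

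BMPRII siRNA, with 3 arrays, gave fewer calls. RASSF2, a RAS-binding tumour suppressor gene, fell 4.20-fold, HNRNPA0, an RNA-binding protein gene, 3.60-fold, DEPP1 3.12-fold, CD34 3.11-fold, CANX, the endoplasmic reticulum chaperone calnexin, 2.78-fold, PGF 2.77-fold, GIMAP4 2.75-fold, FAM89A 2.66-fold and the linker histone gene H1-10 2.65-fold. The largest rises were in CLDN1, an epithelial claudin (3.46-fold), RGS4, a regulator of G protein signalling (3.02-fold), MET (2.94-fold), the non-coding RNA gene SNAR-A1 (2.73-fold) and NPPB, which encodes B-type natriuretic peptide (2.61-fold). They were followed by STAMBPL1 (2.55-fold), the smooth muscle calponin gene CNN1 (2.5-fold), CLIC3 (2.44-fold), TENM3 (2.40-fold) and the secreted protease gene ADAMTS1 (2.40-fold). The call of SNAR-A1 was lost without BMPRII replicate 1 or 3. The count was 591 of 13497 features (4.38%), 264 higher and 327 lower, with 67 changed over 2-fold (25 higher, 42 lower).

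Endothelial function genes fell, with 6 of 31 members lower, 1 higher and a median of -0.22 (camera adjusted p = 6.48e-05; adjusted p = 0.0159 with an estimated correlation). Adjusted over the list alone, 11 were lower and 2 higher. SOX18 fell by 1.38 ± 0.15, LMO2, a transcriptional cofactor of endothelial and blood cells, by 0.88 ± 0.13 and the shear-responsive KLF2 by 0.79 ± 0.12, whereas PTGS2, cyclooxygenase 2, rose by 0.84 ± 0.13. Junction genes were lower in 7 of 22 cases and higher in none, or in 9 and 1 adjusted over the list alone (adjusted p = 0.00139; adjusted p = 0.0212 with an estimated correlation), with CGNL1 (-1.17 ± 0.13), GJA4 (-0.94 ± 0.16), the platelet endothelial adhesion molecule gene PECAM1 (-0.66 ± 0.11) and ESAM (-0.56 ± 0.12) among them. Angiogenesis genes fell in 7 of 35 cases and rose in 3, or 11 and 4 adjusted over the list alone (adjusted p = 0.00139; adjusted p = 0.02 with an estimated correlation), with IGFBP3, an insulin-like growth factor binding protein, higher by 1.08 ± 0.10. The PPARγ target list fell (3 of 16 lower, none higher, or 5 lower adjusted over the list alone; median -0.32, adjusted p = 6.48e-05 and adjusted p = 0.0159 with an estimated correlation), through APLN, the liver X receptor gene NR1H3 (-0.69 ± 0.10) and the partner receptor gene RXRA (-0.57 ± 0.13).

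Smooth muscle markers were higher, with 3 of 11 measured members higher and none lower, or 4 higher adjusted over the list alone (adjusted p = 0.00612; adjusted p = 0.046 with an estimated correlation). CNN1 rose by 1.32 ± 0.20, ACTG2, a smooth muscle actin gene, by 0.89 ± 0.21 and the myosin light chain gene MYL9 by 0.68 ± 0.17. ACTG2 and MYL9 lost their calls under 6 and 12 of 17 alternatives, with adjusted p up to 0.137 and 0.131, among them without BMPRII replicate 1 or without BMPRII replicate 3. Cell cycle genes had a median of 0.31, with 4 of 37 higher and none lower (adjusted p = 8.94e-07; adjusted p = 0.185 with an estimated correlation), or 11 higher and 1 lower adjusted over the list alone. The called members were CDK1 (0.58 ± 0.12), GINS2 (0.48 ± 0.10), UBE2C (0.46 ± 0.10) and KIF11 (0.43 ± 0.11), and each of the 4 lost its call without BMPRII replicate 1 and without BMPRII replicate 3. Cholesterol synthesis genes rose in 2 of 23 cases, or 3 adjusted over the list alone (adjusted p = 0.0123; adjusted p = 0.287 with an estimated correlation), through HMGCS1 (0.61 ± 0.12) and MVK (0.60 ± 0.13), and this list lost its call without control replicate 2. HMGCS1 and MVK, like ESAM above, lost their calls without BMPRII replicate 1 or 3, and RXRA under 8 of 17 alternatives.

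BMP and SMAD targets did not pass camera after BMPRII siRNA (1 of 18 higher, 1 lower, adjusted p = 0.271). SMAD7 rose by 0.53 ± 0.11 and LFNG fell by 0.55 ± 0.12, and among pathway components BMP4 alone, of 20 measured, was called (-0.47 ± 0.10, list adjusted p = 0.715). These 3 genes lost their calls without BMPRII replicate 1 or 3. Interferon genes were not called in any of 35 cases, with a list median of 0.15 (adjusted p = 0.259). Which arrays were used decided this result. Without control replicate 1, control replicate 4 or BMPRII replicate 1 the interferon list was called higher (adjusted p = 0.0195, 0.00901 and 0.033), and without both control replicates 1 and 4, an alternative chosen after seeing the data, its median was 0.488 (adjusted p = 3.62e-07). Without control replicate 3 or BMPRII replicate 2 the median was below 0 (-0.099 and -0.05) and not called. These adjusted p-values of the interferon list are from camera at the preset correlation. Its estimated correlation was 0.731, and with that the adjusted p on all arrays was 0.809 (0.664 by fry). The count of BMPRII calls varied with the arrays used. It was 216, 374 and 248 without BMPRII replicates 1, 2 and 3, and 197 when only the control and BMPRII arrays were fitted.

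**Figure D2:**
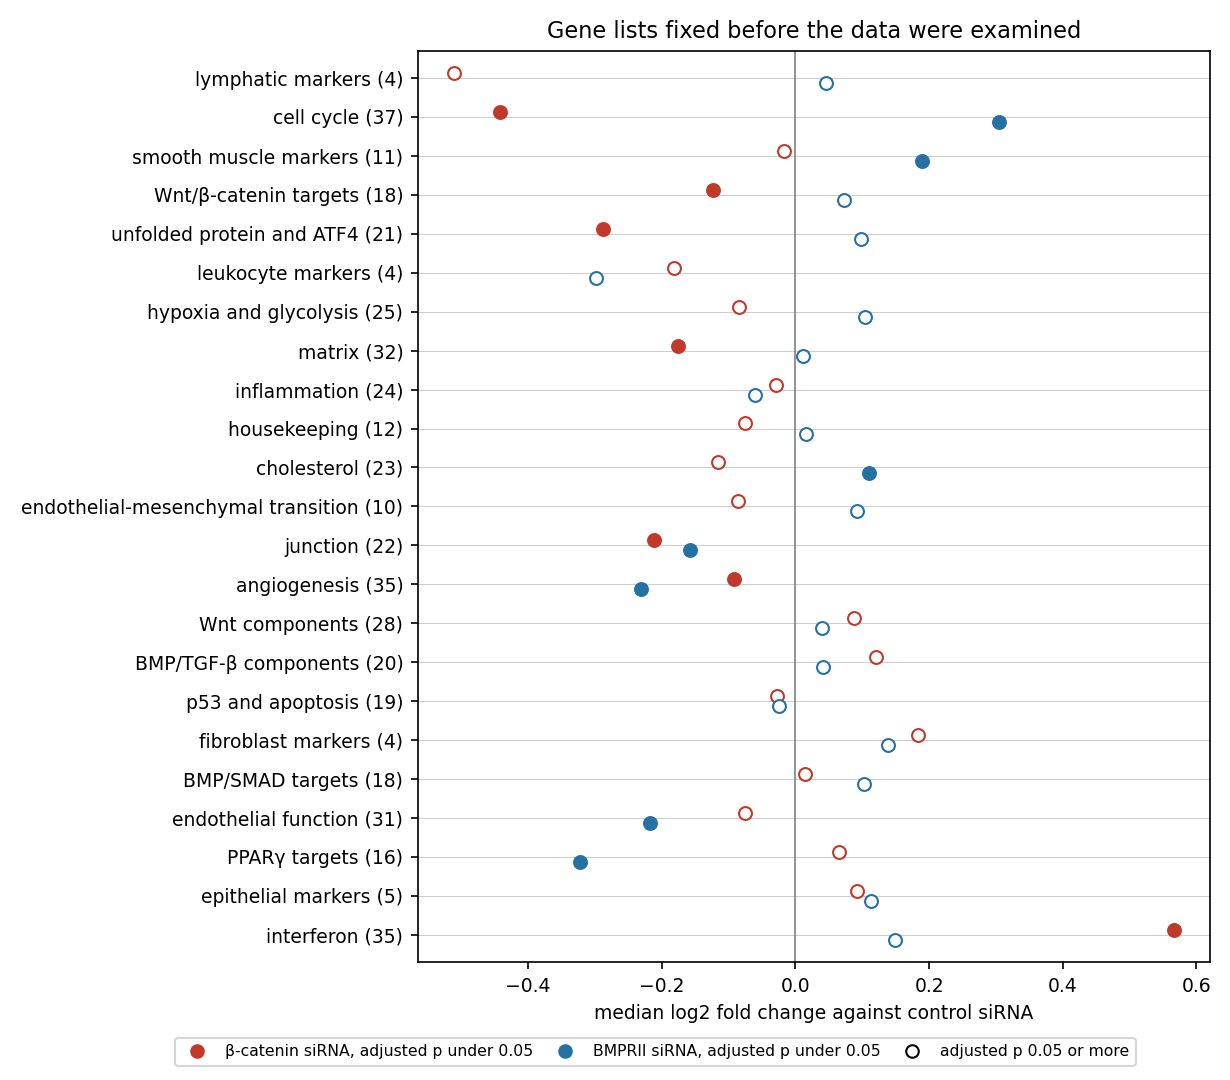
Median log2 fold change of each gene list against control siRNA, red for beta-catenin siRNA and blue for BMPRII siRNA, with the number of measured genes in brackets. Filled points passed camera at an adjusted p under 0.05 with the preset correlation. The cell cycle list lay at -0.44 and 0.31, and the interferon list at 0.57 and 0.15.

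The direct comparison of the knockdowns, which does not involve the control level, asks where their effects differed. CLIC3 (6.26-fold), GTF2H5 (5.74-fold), TENM3 (5.61-fold), POGLUT3 (5.28-fold) and COX7A2 (5.04-fold) were the genes with the largest excess in BMPRII-depleted over beta-catenin-depleted cells. Besides BMPR2 itself, H2BC5 (5.25-fold), GJA4 (4.89-fold) and CD14, a co-receptor for bacterial lipopolysaccharide (4.47-fold), were lower after BMPRII siRNA. MAL2, detected only after beta-catenin siRNA, was at least 3.11-fold lower. Of 13497 features, 2441 differed, 1275 higher and 1166 lower after BMPRII siRNA, and 348 of them over 2-fold (221 higher, 127 lower). Of 2406 calls in the authors' processed table, 62.4% were higher, against 52.2% here. Without BMPRII replicate 1 the count was 1615.

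The cell cycle list had the smallest adjusted p among the lists by camera at the preset correlation (adjusted p = 2.15e-18). With an estimated correlation its adjusted p was 0.0604, a value that other lists shared. Of its members, 32 of 37 were higher after BMPRII than after beta-catenin siRNA and none was lower (median 0.75). The mean of the list was -0.50 to -0.45 on the 4 beta-catenin arrays and 0.27 to 0.30 on the 3 BMPRII arrays relative to the control mean, with the control arrays between -0.22 and 0.17. The unfolded protein and ATF4 list was higher in 9 of 21 members and lower in 1 (adjusted p = 9.36e-05; adjusted p = 0.0604 with an estimated correlation), with ASNS changing by -0.58 and 0.92 and PHGDH by -0.91 and 0.55 in the beta-catenin and BMPRII knockdowns. The rise of PHGDH after BMPRII siRNA lost its call under 13 of 17 alternatives, and the list was not called there (adjusted p = 0.0983). Wnt and beta-catenin targets were higher after BMPRII siRNA in 7 of 18 members and lower in 2, smooth muscle markers higher in 6 of 11, matrix genes higher in 8 of 32 and lower in 1, and cholesterol genes higher in 6 of 23. Their adjusted p was 0.00514, 0.00144, 0.00561 and 0.000725 in that order, and the adjusted p with an estimated correlation 0.0604, 0.0604, 0.145 and 0.177. Adjusted over the list alone, the counts higher were 33 for the cell cycle, 13 for unfolded protein and ATF4, 9 for Wnt targets, 7 for smooth muscle, 10 for matrix and 6 for cholesterol. Interferon genes were lower in 9 of 35 (adjusted p = 0.000145; adjusted p = 0.593 with an estimated correlation).

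**Figure D3:**
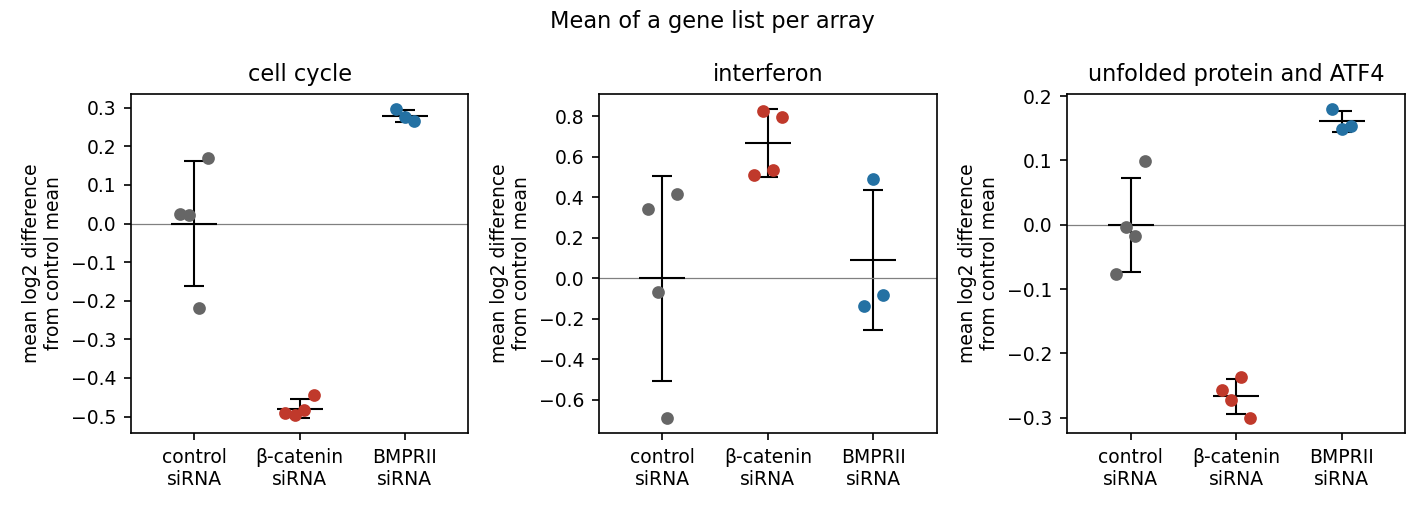
Mean log2 difference from the control mean for the cell cycle, interferon and unfolded protein and ATF4 lists on each array. Points are arrays, and bars are the mean and SD of the group (n = 4, 4 and 3). The cell cycle means do not overlap between groups, while the interferon means of the control arrays run from -0.69 to 0.42.

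Genes called in both knockdowns were then compared. CD34 (-1.77 and -1.64 after beta-catenin and BMPRII siRNA), RASSF2 (-1.45 and -2.07), SOX18 (-1.43 and -1.38) and PGF (-1.35 and -1.47) were among the strongest falls seen in both, and MET (1.59 and 1.56), STAMBPL1 (1.06 and 1.35), ISOC1 (1.12 and 0.94) and GATC (0.94 and 0.85) among the strongest rises. CCM2L, a homologue of a cerebral cavernous malformation gene, was not detected on any beta-catenin array, fell at least 2.46-fold there and changed by -1.30 after BMPRII siRNA. FLRT3 was not detected on any control or BMPRII array. The calls of STAMBPL1 after BMPRII siRNA were lost without any of the BMPRII replicates in turn, and those of ISOC1 without BMPRII replicate 1 or 3. CLIC3 (-1.36 and 1.29), TENM3 (-1.23 and 1.26), NIBAN1 (-1.21 and 1.02), PCK2 (-1.0 and 0.93) and SPOCD1 (-0.90 and 0.96) fell after beta-catenin siRNA and rose after BMPRII siRNA. The reverse held for GJA4 (1.35 and -0.94), CD14 (1.34 and -0.82), STAT4 (1.07 and -0.75), GBP4 (0.73 and -0.86) and LPCAT2 (0.71 and -0.91). After BMPRII siRNA the calls of CD14, STAT4 and GBP4 were lost under 3, 3 and 5 of 17 alternatives, among them without BMPRII replicate 3 in each case, and that of NIBAN1 under 1.

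In numbers, 115 features were lower in both, where independent lists of these lengths give 30.9, and 77 were higher in both, where they give 25.4. Opposite calls numbered 46 lower after beta-catenin and higher after BMPRII siRNA (25 for independent lists) and 30 the other way (31.5). Without BMPRII replicates 1, 2 and 3 the features called in the same direction fell from 192 to 78, 119 and 85, and those in opposite directions from 76 to 30, 42 and 33. The latter numbered 46, 50 and 50 without beta-catenin replicates 1, 2 and 3. Because both contrasts use the same controls, unchanged groups were simulated against them 100 times. These gave on average 28.2 features lower in both and 26.5 higher, with up to 1185 and 1015 in a single simulation. Shared controls work against opposite calls, of which the simulations gave 0.04 and 0.01 on average in the order above, and at most 4 and 1. With the 4 controls split into pairs, so that no array was shared, the 6 splits gave 42 to 89 features lower in both (2.82 to 5.10 times independent lists) and 10 to 59 higher (1.36 to 3.30 times). Opposite calls in these splits, both kinds together, numbered 32 to 90 and exceeded independent lists in each of the 6. Relative to independent lists the excess was largest with controls 1 and 2 for beta-catenin siRNA (59 against 21.8). It was smallest with controls 1 and 4 for beta-catenin siRNA (61 against 37.4). Log2 fold changes correlated at 0.287 across features, which are not independent, against 0.562 on average in the simulations (0.03 to 0.945) and -0.015 to 0.12 with split controls. Their covariance was 0.0294 against a simulated 0.0212 (0.000791 to 0.101).

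**Figure D4:**
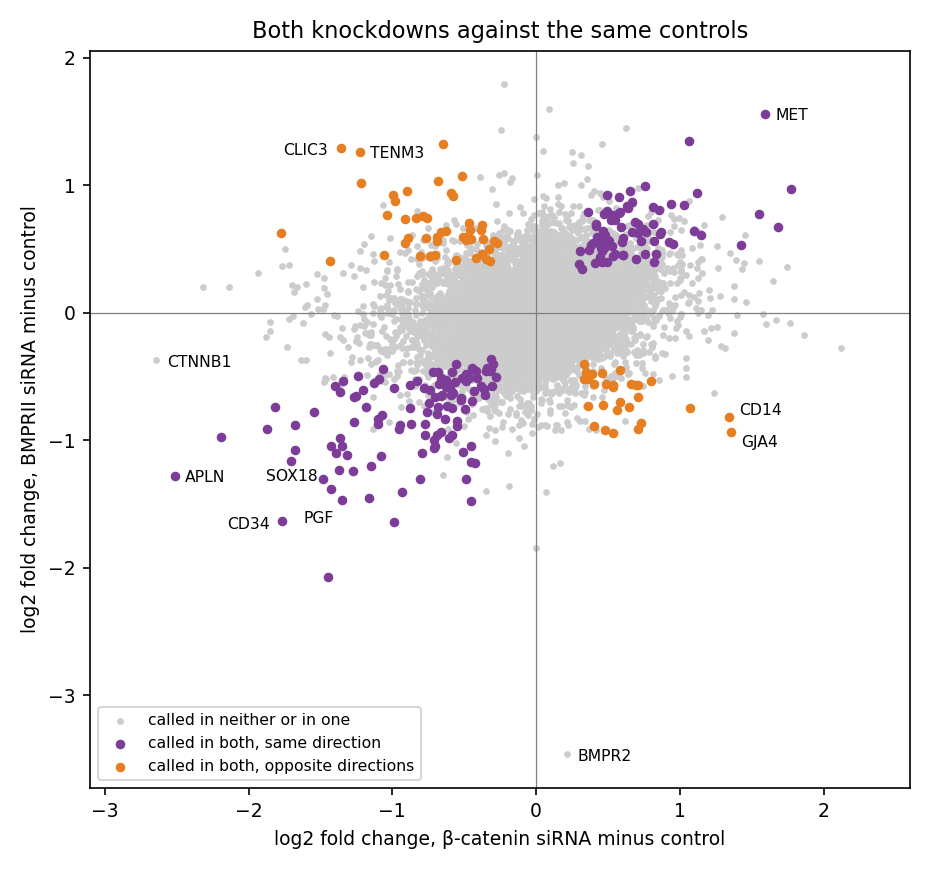
Log2 fold change of each tested feature after beta-catenin siRNA (horizontal) and BMPRII siRNA (vertical) against the same controls. Purple points were called in both in the same direction (192 features) and orange points in opposite directions (76), and grey points in neither or only in a single knockdown.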

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

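The test of the cell cycle list between the knockdowns was chosen after its result was seen. The tests without control replicates 1 and 4 were written down before their results were seen.

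Cell cycle genes moved apart in the knockdowns, with a median of -0.44 after beta-catenin siRNA, 0.31 after BMPRII siRNA and 0.752 in their difference, by which the list came to notice, so setting it against random lists decides nothing. Control replicates 1 and 4, which correlated least with the other arrays, were the highest controls for this list (0.026 and 0.171), so they cannot have made the BMPRII rise (0.404 without them), and without them the fall after beta-catenin siRNA was still -0.392. Control replicate 3 was the lowest at -0.219, and without it the median after BMPRII siRNA was 0.24 (adjusted p = 0.000323). With an estimated correlation, which was 0.193 for this list, its adjusted p was 0.0604, and the cause of that loss was not tested. The Wnt target and smooth muscle lists had the same adjusted p at estimated correlations of -0.019 and -0.035, below the preset 0.01. Their unadjusted camera p rose from 0.00144 to 0.00873 and from 0.000287 to 0.0052. For these lists a higher correlation between genes therefore cannot be what raised p. A difference in growth state between cultures, caused by the knockdown or by plating and serum withdrawal on separate days, may lie behind the cell cycle pattern. The labels give nothing to separate these.

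Opposite calls form the other difference between the groups. The direct comparison called all 76 features that the knockdowns had changed in opposite directions. That follows from how they were chosen, since their difference adds up both called effects, and it supports nothing further.

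In groups of 4, single arrays lay far from the other 3 for 12 of 336 values tested (280 of them gene values), which is 3.6% where chance gives about 5%. Control replicate 4 was the lowest for 5 of the 6 control values. The gap to the nearest array, as a share of the group's range, was 0.977 for SOX18, 0.959 for ESAM, 0.935 for COX7A2, 0.855 for GTF2H5 and 0.847 for CLIC3. Control replicate 3 was the lowest for MMP14 (0.874). In the beta-catenin group, replicate 2 was the highest for CX3CL1 (0.943) and the lowest for CCND1 (0.878). Replicate 1 was the highest for DEPP1 (0.917), replicate 4 the lowest for MVK (0.879) and MGLL (0.863), and replicate 3 the lowest for ACVRL1 (0.846).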

How the results depend on the processing

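Leaving out control replicates 1 and 4 was chosen after seeing the data, and all other alternatives were fixed before the data were examined. The chip as a block was not run, since the files used here name no chips. No called list or named gene changed sign under any alternative run. Of those not called, 18 of 49 list medians and 1 of 3 genes did in at least 1, among them the interferon list after BMPRII siRNA (0.149, lowest -0.099) and ID1 after BMPRII siRNA (-0.066, range -0.185 to 0.047). CTNNB1 and BMPR2 stayed called in the 17 alternatives run for single genes. The count after beta-catenin siRNA stayed within 1.5 times of 2578 (1801 to 2627 with single samples left out, 1948 without control replicates 1 and 4). The count after BMPRII siRNA (591) was 197 with only the 2 groups in the fit and 216 to 655 with single samples left out, where fewer samples were fitted, and 555 without control replicates 1 and 4. Features that differ between the knockdowns (2441) numbered 3779 with array weights, the cause of which was not tested, and 1615 to 3150 with single samples left out. The control arrays enter this contrast only through the processing and the shared spread. It gave 3398 with only the 2 knockdown groups in the fit and 3560 without control replicates 1 and 4. Features called in both in the same direction (192) were 78 to 220, and in opposite directions (76) 30 to 79, with single samples left out, and the latter 47 without a filter. With the controls split into pairs, which leaves fewer samples per contrast, the former were 73, 71, 82, 52 and 74 in 5 of the 6 splits and the latter 35, 46 and 32 in 3 of them. With an estimated correlation, 0 lists were called after beta-catenin siRNA (8 with the preset value) and 0 between the knockdowns (9). The cause was not tested. The Wnt target list lost its call in both contrasts at an estimated correlation of -0.019, below the preset 0.01.

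Replicate numbers did not pair the samples. Over 10 pairs of arrays with the same number in different groups, the correlation of deviations from the group means was -0.05 to 0.06, and 0 pairs exceeded 0.1. With the number as a block, 320 features were called after BMPRII siRNA, 102 in both knockdowns in the same direction and 42 in opposite directions. The interferon list was then called higher after BMPRII siRNA (adjusted p = 0.0133 at the preset correlation). The block uses up 3 degrees of freedom.

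Of 71 called genes named after BMPRII siRNA, 40 stayed called in every one of 17 alternatives and 31 lost the call in at least 1. The fit of only the control and BMPRII arrays, not among the 17, kept 195 of the 591 features called after BMPRII siRNA. After beta-catenin siRNA 91 of 101 stayed called wherever they could be tested, which was in 14 alternatives for FLRT3 and AKR1C2 and 13 for PCDH12, and between the knockdowns 10 of 10. Whether precision differed for genes near background was not tested.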

Other observations

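The tests of a response to any targeting siRNA and of a lower share of endothelial cells were chosen after their results were seen. The other tests in this part were written down before.

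The list of the siRNA targets was called after BMPRII siRNA (adjusted p = 8.24e-05) and not after beta-catenin siRNA (adjusted p = 0.118), and the list of the 2 measured genes of the question after both (adjusted p = 0.000986 and 0.0279; adjusted p = 0.103 and 0.196 with an estimated correlation). The latter lost its BMPRII call without control replicate 1, without a filter and in the authors' processed table (adjusted p up to 0.388). The siRNA target list holds the silenced gene itself, so a fall in it was built in. Both lists are among the 25 in all counts of lists called. By fry 19, 15 and 17 of 25 lists passed after beta-catenin siRNA, after BMPRII siRNA and between the knockdowns, against 8, 9 and 9 by camera. The cholesterol list after BMPRII siRNA and the interferon list between the knockdowns passed camera but not fry (adjusted p = 0.055 and 0.0891). Several lists went both ways or missed the threshold. After beta-catenin siRNA, 5 of 24 inflammation genes fell and none rose (adjusted p = 0.067). CXCL8, interleukin 8, changed by -1.13 ± 0.27 (log2 fold change ± SE), the chemokine genes CX3CL1 by -1.12 ± 0.20 and CXCL6 by -0.70 ± 0.18, and E-selectin, SELE, which was not detected on any beta-catenin array, fell at least 2.08-fold. Of 23 cholesterol and fatty acid genes 4 fell (adjusted p = 0.067), INSIG1 by 1.23 ± 0.12, MVD by 0.77 ± 0.10, FASN by 0.77 ± 0.22 and FADS1 by 0.54 ± 0.12. Hypoxia and glycolysis genes divided, with 4 of 25 higher and 5 lower (adjusted p = 0.523). SLC2A3, a glucose transporter gene, and ADM, adrenomedullin, rose by 1.12 ± 0.13 and 0.75 ± 0.08, while PGAM1 and BNIP3L fell by 0.98 ± 0.10 and 0.50 ± 0.10. Among p53 and apoptosis genes 2 of 19 rose and 3 fell (adjusted p = 0.602), with DDB2 at -1.13 ± 0.15. TP53INP1 changed by 0.58 ± 0.10 after beta-catenin siRNA and by -0.70 ± 0.11 after BMPRII siRNA, where ZMAT3 also fell (-0.55 ± 0.11, list adjusted p = 0.778). Of 28 Wnt pathway components, 4 rose and 1 fell after beta-catenin siRNA (adjusted p = 0.618). DAAM1 (0.82 ± 0.09), FZD8 (0.72 ± 0.14) and FZD2 (0.58 ± 0.13) rose and DKK3 fell (-0.33 ± 0.08). After BMPRII siRNA FZD2 (0.78 ± 0.14) and DAAM1 (0.40 ± 0.10) rose (adjusted p = 0.413). After BMPRII siRNA, LOX, a collagen cross-linking enzyme, rose by 1.02 ± 0.15 and was, with ADAMTS1, called among 32 matrix genes (adjusted p = 0.714). It was the called member among 25 hypoxia genes (adjusted p = 0.127). In that knockdown 2 of 24 inflammation genes fell (adjusted p = 0.342), VCAM1 by 0.79 ± 0.18 and LTB by 0.96 ± 0.20. In the unfolded protein and ATF4 list 3 of 21 rose and 1 fell, or 5 and 1 adjusted over the list alone (adjusted p = 0.0983), with SLC7A11 at 0.65 ± 0.13 and DDIT4 at -0.53 ± 0.11. The Wnt target list held 1 rise and 2 falls, or 4 and 2 adjusted over the list alone (adjusted p = 0.235), with VCAN at 0.87 ± 0.14 and SOX17 at -0.42 ± 0.11. Of these BMPRII calls, those of SOX17, DAAM1, VCAM1, DDIT4, LTB, ZMAT3 and SLC7A11 were lost under 13, 12, 7, 5, 3, 2 and 1 of 17 alternatives. Of the beta-catenin calls above, FASN was lost under 5, with a change as small as -0.359, and CXCL8, FZD2 and DKK3 under 1 each.

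Markers of other cell types were measured for few genes. Of leukocyte markers 4 of 12 on the array could be tested. LAPTM5 fell in both knockdowns (-1.27 ± 0.16 and -0.66 ± 0.17), the latter a call lost under 15 of 17 alternatives with adjusted p up to 0.194, and CD14 rose after beta-catenin siRNA and fell after BMPRII siRNA (list adjusted p = 0.719 and 0.147). Of 4 fibroblast markers COL3A1 rose after beta-catenin siRNA (0.70 ± 0.11, adjusted p = 0.197), and none was called after BMPRII siRNA (adjusted p = 0.778). Of 5 epithelial keratin and adhesion markers KRT19 (1.06 ± 0.12) and KRT7 (0.43 ± 0.11) rose after BMPRII siRNA (adjusted p = 0.125), KRT7 with its call lost under 13 of 17 alternatives, and KRT7 fell after beta-catenin siRNA (-0.42 ± 0.10, adjusted p = 0.832). Of 4 lymphatic markers LYVE1 and NRP2 (-1.03 ± 0.18) fell after beta-catenin siRNA (adjusted p = 0.0621), and LYVE1 fell after BMPRII siRNA (adjusted p = 0.806). The lymphatic list was higher after BMPRII than after beta-catenin siRNA in 3 of 4 members (adjusted p = 0.0221; adjusted p = 0.114 with an estimated correlation). Of 11 smooth muscle markers TAGLN (-0.34 ± 0.08) and RGS5 (-0.61 ± 0.15) fell after beta-catenin siRNA (adjusted p = 0.357), TAGLN with its call lost without beta-catenin replicate 4. Of 10 genes of endothelial-to-mesenchymal transition FN1, fibronectin, rose after beta-catenin siRNA (0.40 ± 0.11, call lost under 5 of 17 alternatives, list adjusted p = 0.719) and none was called after BMPRII siRNA (adjusted p = 0.217). Among 12 housekeeping genes HPRT1 rose (0.44 ± 0.10) and YWHAZ fell (-1.08 ± 0.11) after beta-catenin siRNA, with the same sign under median scaling and in the authors' processed table, and none was called after BMPRII siRNA (adjusted p = 0.197 and 0.715). The call of HPRT1 was lost without both control replicates 1 and 4.

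Features lower in both knockdowns, CD34 and SOX18 among them, may reflect an effect shared by them, fewer endothelial cells, or the controls they share. With the controls split into pairs, the number lower in both was at least 2.82 times that of independent lists in all 6 splits. An excess over independent lists thus remained where no control array was shared. Opposite calls also exceeded independent lists in each split, from 61 against 37.4 with controls 1 and 4 for beta-catenin siRNA to 59 against 21.8 with controls 1 and 2. An excess is thus not confined to a shared fall, but in each split it was larger for features lower in both. Unchanged groups were not simulated with split controls, so how much of the overlap the shared controls made stays open. If only the other cell types expressed their markers, a lower share of endothelial cells would raise those of every type alike. After beta-catenin siRNA 4 of 24 smooth muscle, fibroblast, leukocyte and epithelial markers fell, of 3 types, and 2 rose. None of these lists passed camera there (adjusted p = 0.197 to 0.832). The arrays do not show which cells express the markers, and endothelial cells that express them could lower them. These falls therefore do not decide on a lower share of endothelial cells in that knockdown. After BMPRII siRNA 2 fell, both leukocyte markers (CD14 and LAPTM5, lost under 3 and 15 of 17 alternatives), and 5 rose (KRT7, MYL9 and ACTG2 lost under 13, 12 and 6, KRT19 and CNN1 under none), while the endothelial function list fell, so a lower share of endothelial cells stays open in that knockdown, although CDH5, the gene of the endothelial cadherin, chosen after its values were seen, differed from control by only -0.01 ± 0.09. An effect that any targeting siRNA has against the control duplex stays open as well. Since each target had 1 reagent, an effect of that reagent on other genes cannot be told apart from an effect of losing its target. Matches of the siRNA sequences to strongly lowered genes, such as GTF2H5, COX7A2, HNRNPA0 and CANX, were not searched.

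The rise of interferon genes after beta-catenin siRNA is a second pattern to weigh. Low values on control arrays 1 or 4 would need those arrays to lie lowest, but they were the highest of the controls (0.34 and 0.42), and all 4 beta-catenin arrays lay above every control array, by 0.096 at the closest. Control replicate 3, at -0.69, was the lowest. A response to any targeting siRNA cannot be told apart from an effect of beta-catenin. The median of the list in BMPRII minus beta-catenin siRNA was -0.498, yet the lowest beta-catenin array lay above the highest BMPRII array by only 0.024, where arrays of a group spread with a pooled SD of 0.369. A response to the duplexes or the transfection that differed between cultures may explain the pattern as well as an effect of beta-catenin.

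Other splits of the samples were counted for each contrast. For the features called after beta-catenin siRNA (2578, highest other split 0), after BMPRII siRNA (591, highest other 42) and between the knockdowns (2441, highest other 0), 1 of 35 splits, the real one, gave as many, the lowest share possible here. At the 0.05 level, with no allowance for the number of counts tested, this speaks against chance in how these arrays were grouped. It says nothing on differences between cultures. A split that mixes the groups puts their difference into the spread, so its low count adds no further weight. For the lists called after beta-catenin siRNA (8, highest other 6) 1 of 35 splits gave as many, which passes the same level, again with no such allowance. The margin over the highest other split was small and 0 of the 8 were called with an estimated correlation, so chance is not firmly excluded for these lists. For those after BMPRII siRNA (9, highest other 10) it was 2 of 35 and between the knockdowns (9, highest other 9) 3 of 35, so for these counts of lists chance is not excluded. The split with 42 features set control replicate 4 beside the BMPRII arrays, apart from the other 3 controls.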
